A study of Mus musculus with 4 samples.

How the data were processed

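Total RNA was extracted with TRIzol and hybridised, as biotin-labelled sense cDNA, to mouse whole-transcript gene arrays (MoGene ST 2.0), per the labels' protocols. The labels give 4 samples, 1 in each combination of genotype (WT or XCR1-deficient) and treatment (LPS with or without recombinant mouse XCL1), and the series' title names the cells as type 1 conventional DCs. The tissue they came from and the length of treatment are not given in the sources used here. The deposited values are log2 signals per gene-level probe set, summarised by RMA per the labels' descriptions. RMA corrects the background, equalises the distributions of the arrays and summarises probes on the log2 scale. The software, its version and the annotation build are not given in the sources used here. The array medians were 5.43 and 5.40 for WT and 5.44 and 5.44 for KO, and the values ran from 2.00 to 13.7, as log2 values do. Sorted values of any pair of arrays differed by up to 0.242, so the distributions were close to each other but not identical. Because RMA equalises the arrays, a shift of most genes in one direction cannot be seen in such values.

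Gene names came from the array's annotation table. Of the 41345 probe sets, 25335 were listed, 23521 of them with 1 gene symbol and 1814 with several, and 16010 were unnamed here. Symbols were looked up by gene ID in a RefSeq table (assembly GRCm38.p6), which held 23328 of them and changed 0. That table also gave the neighbours of Xcr1 within 5 Mb and the chromosome of each gene. No coordinates are given, since the build of the array annotation is not named. Probe sets with several symbols, and 5104 of predicted or unnamed genes, small RNAs, receptor segments and olfactory receptors, were left out of the counts, with an alternative that kept them. For a gene with several probe sets, the one with the highest mean over the arrays was used. This left 17259 genes, of which 11060 had a signal of at least 5.43, the median of all values, on at least 1 array, and 794 of these had more than 1 probe set. Over 440 genes with several probe sets past the limit, the SD per probe set was 0.178 to 0.230 in the 4 pairs of arrays. It was derived from the difference between probe sets of a gene, whose own SD is larger.

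The comparisons were XCL1 in WT, XCL1 in KO, their difference, KO against WT with LPS, KO against WT with LPS and XCL1, and the genes that differed in both genotype pairs. Each is a log2 difference between single arrays, and no test was run. An additive model of genotype and treatment over the 4 arrays, which would take the difference between the XCL1 effects as error, was not fitted. The table holds no detection flags, so the limit on signal is not a measured background. A fold against a signal below it is given against the limit as "at least". Log2 differences are as measured unless they are said to be against the limit. Genes were counted at 1.5-fold, and overlaps between pairs are given with the number that independent lists of those lengths would share. The XCL1 pairs share no array with each other, nor do the genotype pairs, but an XCL1 difference and a genotype difference share an array. The 32 gene lists, the rule for named genes, the threshold and the alternatives were fixed before the data were examined. For a list, the median difference of its members past the limit was placed among 10000 random lists of the same size, drawn within 10 bins of mean signal, which describes these arrays only. Lists without a value in the report or in the closing section lay inside the central 95% in each of the 5 comparisons.

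Genes were named by rule as the 12 with the largest positive and negative differences for XCL1 in WT and for the difference between WT and KO, 6 and 6 for XCL1 in KO, and 12 and 12 by the smaller of both genotype differences. Xcr1, Xcl1, up to 4 members of each list and the neighbours of Xcr1 at 1.5-fold were added. Other members of lists, second probe sets and sex-linked genes were chosen after their values were seen, as were Ido1 and Nos2 beside the interferon genes.

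The counting was tested on simulated pairs of arrays with 200 changed genes among 11060. Noise was drawn from a normal distribution, its SD taken within bins of mean signal from the central spread of the KO pair. The counting recovered 49.5% of genes changed exactly 1.5-fold, 98.6% at 2-fold and 100% at 3-fold, with 42.3, 43.5 and 39.4 false calls on average over 20 pairs. Wider tails in the real differences were not simulated, so these false calls are no error rate of the real counts. Of 200 simulated unchanged lists of 15 genes, 4% fell outside the central 95%, and a shift of 0.3 was found in 100%. The simulated genes varied independently, which the genes of a real list need not do.

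Alternatives were a 2-fold threshold, no limit on signal, a stricter limit (6.91, the 75th percentile), cyclic loess between arrays (span 0.7, 3 iterations), centring each array on the median of its genes past the limit, the mean of a gene's probe sets, predicted genes and small RNAs kept, and the mean in place of the median of a list. Raising signals below the limit to the limit, leaving out genes of chromosomes X and Y, leaving out the lymphoid and red cell lists, and 3 further gene lists were added after seeing the data. Cyclic loess was run in R 4.3.3 with limma 3.58.1. All else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.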

Results

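Gene expression was measured on 4 microarrays in mouse type 1 conventional dendritic cells (cDC1), the subset that takes up dead cells and presents their antigens to CD8 T cells. Wild-type (WT) and XCR1-deficient (KO) cells of the C57BL/6 strain had received lipopolysaccharide (LPS, 100 ng/ml), a bacterial ligand of Toll-like receptor 4, or LPS together with recombinant mouse XCL1 (100 ng/ml). XCL1 is the chemokine ligand of XCR1, a receptor found mainly on cDC1. Each of the 4 groups had 1 array, from mice aged 10 weeks that the labels give as female, so the number of arrays limits the precision and no difference below has a replicate check, an error or a p-value. A gene is called higher or lower where 2 arrays differed at least 1.5-fold (0.58 on the log2 scale), among 11060 named genes with a signal above a fixed level. All values are log2 array signals or their differences. The 4 arrays resembled each other closely, with correlations across genes from 0.983 to 0.993, and genes are not independent replicates.

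The targeted gene, Xcr1, gave a log2 signal of 6.42 on the WT array with LPS and 7.19 on the WT array with LPS and XCL1. Its signal was 5.54 and 5.11 on the corresponding KO arrays, close to the expression limit of 5.43. Xcr1 was therefore 1.83-fold lower in the KO with LPS. With LPS and XCL1 its KO signal lay below the limit, and it was at least 3.38-fold lower when measured against the limit. This is the direction the genotype labels give. Where the deletion lies is not in the labels, and a probe outside it would check nothing. Signals of Xcl1, the ligand gene, were 7.91 and 7.93 in WT and 7.59 and 7.70 in KO. Among 52 genes starting within 5 Mb of Xcr1, none differed 1.5-fold between the genotypes with LPS. With LPS and XCL1, Ccr8 and Xirp1 were higher in the KO, both with WT signals below the limit, and neither was so in both pairs. Measured against the limit, the Ccr8 difference was 0.43, within 1.5-fold.

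The first comparison asked what XCL1 added to LPS in cells that carry its receptor. Few genes differed, and most of them were dim. With XCL1, 25 genes were higher and 37 lower, 62 in all or 0.561% of the genes, and 2 of them differed 2-fold. These 2 were Defb2, a beta-defensin (1.29), and Dcpp3 (-1.13), each with its lower signal under the limit, at 4.62 and 4.38. With signals below the limit raised to it, the differences were 0.49 and -0.09, and 27 genes in all reached 1.5-fold, 13 higher and 14 lower. The other genes named by a fixed rule were within 1 log2 unit. They included Gemin6, a member of the SMN complex (0.97), Xcr1 itself (0.77), Rabggtb, a subunit of the Rab prenylating enzyme (0.79), P3h1, a collagen prolyl hydroxylase (0.73), and Sec61b, a subunit of the protein translocation channel (0.69). Zfp954, Smok2a, Ubxn2b, Zfp872, Zfp930 and Coq10a completed the higher genes, at 0.84, 0.79, 0.69, 0.68, 0.68 and 0.68. Lower with XCL1 were Qrfprl (-0.84), Sim1 (-0.79), Tcam1 (-0.79), the GTP cyclohydrolase regulator Gchfr (-0.77), the beta-catenin cofactor Bcl9l (-0.75), Ptma-ps2 (-0.73), the chemokine receptor Ccr8 (-0.71), Gpr161 (-0.69), Dlk2 (-0.68) and the globin Hbq1b (-0.67). Sly was lower by the same measure (-0.72), and is read by 6 probes of a gene with several copies. A second probe of Gemin6 gave 0.29. Of the genes named here, Gemin6, Smok2a, Rabggtb, Xcr1, P3h1, Ubxn2b, Zfp930, Coq10a, Qrfprl, Bcl9l and Hbq1b still differed 1.5-fold with dim signals raised to the limit.

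Genes of cDC1 maturation and inflammation stayed below the threshold with XCL1 in WT. No member of the lists for cDC1 identity, maturation, co-stimulation, inflammatory cytokines, NF-kB targets, chemokines, interferon-stimulated genes or antigen presentation reached 1.5-fold. Cd40, Cd86 and Cd83 differed by 0.02, 0.02 and 0.04, and Ccr7, the receptor for lymph node homing, by -0.13. Of the 32 lists fixed in advance, 6 had a median outside the central 95% of 10000 random lists of equal size and signal. If the genes of a list varied independently, 1.6 were to be expected, and related genes need not do so. Inflammatory cytokines had a median of -0.07 (percentile 0.09), with 4 of 20 members above 0 and Il1b at -0.35, Tnfsf15 at -0.32 and Il6 at -0.17. Glycolysis lay above the random lists at 0.14 (percentile 99.4), with 11 of 13 members above 0, among them Pgam1 at 0.29, Hk1 at 0.27 and Slc2a1 at 0.24. The hypoxia list was at 0.18 (percentile 99.2), with Ddit4 at 0.41. Apoptosis and survival genes (-0.08, percentile 0.35), T cell markers (-0.14, percentile 0.86) and stromal markers (-0.16, percentile 1.80) lay below. With the mean of a list in place of its median, glycolysis (0.11, percentile 97.2), hypoxia (0.14, at the edge), apoptosis (-0.0068, percentile 23.9), T cell (-0.06) and stromal (-0.10) lists lay inside the random range. The hypoxia list was also inside with the stricter limit on signal (0.12) and with the mean of probe sets (0.11), T cell markers with the stricter limit (-0.13) and stromal markers with no limit (-0.13). No member of these 6 lists differed 1.5-fold, though 1 apoptosis gene did with cyclic loess. Of the 62 genes, 41 had a mean signal under 6 and 1 of 3090 genes with a mean of at least 8 was called. With a stricter limit on signal the count was 11, and centring each array on its gene median gave 13 higher and 65 lower genes. Centring moved each list median by -0.07 too, to 0.07 for glycolysis, and left the percentiles as they were.

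The same treatment in cells without the receptor asked which differences arise when XCL1 cannot act through XCR1. The KO pair held more called genes than the WT pair, with 50 higher and 60 lower, 110 in all or 0.995%, and 6 at 2-fold. Rabggtb was 3.70-fold higher, from 6.31 to 8.20. The other higher genes named were Snhg17, a small nucleolar RNA host gene (1.04), the interferon-inducible tetherin gene Bst2 (0.97), the autophagy gene Gabarapl1 (0.95), Pet100 (0.93) and the proteasome subunit Psma5 (0.88). Lower were Hamp, which encodes hepcidin (-1.21), Ly6d, a marker of B cell and plasmacytoid DC lineages (-1.12), the type I interferon Ifna4 (-1.08), Dcpp1 (-0.97) and Ly96, the LPS co-receptor MD-2 (-0.94). Aanat was lower as well, at 4.56 with XCL1 and 5.56 without. Of the other 2 probe sets of Snhg17, 1 gave 1.04 and 1 gave 0.15, and a second probe set of Psma5, below the limit, gave -0.03. With signals below the limit raised to it, Aanat and Dcpp1 were within 1.5-fold (-0.13 for both), and 65 genes reached it, 36 higher and 29 lower. Medians of 8 lists lay outside the central 95%. Above were NF-kB targets (0.11), interferon-stimulated genes (0.10), MHC class I presentation (0.13), glycolysis (0.14) and cytoskeleton and migration (0.13). Below were cDC1 identity (-0.04), immediate early genes (-0.03) and B cell markers (-0.06). The immediate early median moved to 0.0385 with the stricter limit on signal, and the means of that list and of B cell markers were above 0, at 0.0137 and 0.0031, inside the random range. The immediate early median was inside with cyclic loess too (-0.04, percentile 8.87). Means of cDC1 identity (-0.0029), NF-kB targets (0.10), glycolysis (0.08) and cytoskeleton (0.09) lay inside as well, as did the glycolysis median with no limit on signal and with the mean of probe sets (0.14 in each). Bst2 was higher, and so was Dusp4 among immediate early genes (0.77). With the stricter limit on signal the count was 26, and with predicted genes and small RNAs kept it was 183. Centring on the gene median gave 25 higher and 88 lower genes and moved each list median by -0.07, to 0.03 for interferon-stimulated genes and 0.04 for NF-kB targets. With cyclic loess cDC1 identity was at -0.08, B cell markers at -0.12 and cytoskeleton and migration at 0.08, all outside the random range still.

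**Figure D1:**
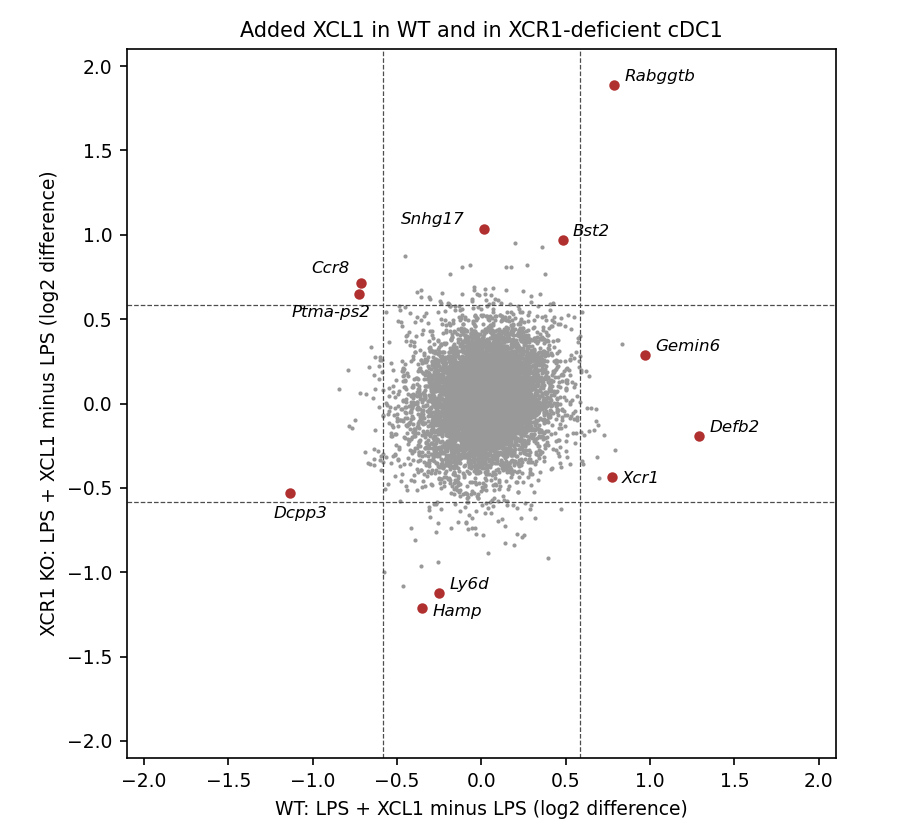
Difference between the arrays with and without XCL1 for each of 11060 genes, as log2 signal with LPS and XCL1 minus LPS, in WT (horizontal axis) and in XCR1-deficient cDC1 (vertical axis), with dashed lines at 1.5-fold and named genes in red. The cloud shows little slope (Pearson r 0.133 across genes), and Rabggtb alone lies beyond 1.5-fold above 0 on both axes.

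Few called genes were shared between the XCL1 differences in WT and KO cells. Rabggtb was the 1 gene higher in both pairs, where independent lists would share 0.113, and no gene was lower in both. Of the 62 genes called in WT, 27 (43.5%) had the same sign in KO. Of the 110 called in KO, 60 (54.5%) had the same sign in WT. Across genes, Pearson's r was 0.133 and Spearman's rho 0.131. Glycolysis was the 1 fixed list with a median above the random lists in both pairs, at 0.14 (percentile 99.4) and 0.14 (percentile 97.7), with 11 and 7 of 13 members above 0. The spread of the differences over all genes was no larger with the receptor than without it, at an SD of 0.175 in WT and 0.196 in KO.

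The difference between the XCL1 effects in WT and KO was at least 1.5-fold in 319 genes, 153 with a higher and 166 with a lower value in WT. It combines 4 arrays and was not tested, and with the stricter limit on signal 71 genes passed the threshold. With signals below the limit raised to it, 205 genes did. The effect in WT was above that in KO for Defb2 (1.48), Nctc1 (1.31), Xcr1 (1.20), Sec61b (1.14), the metallothionein Mt2 (1.10), Smok2a (1.07), Btbd35f17 (1.03), the osteocalcin gene Bglap (1.03), Clpsl2 (1.03), Dact3 (1.00), Zfp872 (1.00) and Megf11 (0.98). It was below for Ccr8 (-1.43), Ptma-ps2 (-1.38), Psma5 (-1.33), the homeobox gene Dlx2 (-1.11), Rabggtb (-1.10), Plekhs1 (-1.07), Aldh1b1 (-1.04), Smim27 (-1.04), Atp6v1g3 (-1.04), Pls1 (-1.03), Snhg17 (-1.02) and Zfp943 (-0.99). Of these, Defb2 (0.49), Nctc1 (0.03), Sec61b (0.26), Btbd35f17 (0.15), Clpsl2 (0.45), Dact3 (0.16), Smim27 (-0.04), Ccr8 (-0.56), Ptma-ps2 (-0.10), Atp6v1g3 (-0.58) and Pls1 (-0.16) stayed within 1.5-fold with dim signals raised to the limit. Others moved too, Xcr1 to 0.88, Smok2a to 0.82, Zfp872 to 0.59, Megf11 to 0.83, Psma5 to -1.26, Dlx2 to -1.01 and Plekhs1 to -0.80. Second probe sets below the limit gave 0.19 for Psma5, 0.16 for Zfp943 and -0.02 for Sec61b, and 2 others of Snhg17 past it gave -1.38 and -0.16. Medians of 3 lists lay below the random lists. They were inflammatory cytokines (-0.16, 2 of 20 members above 0), NF-kB targets (-0.11, 5 of 20 above 0) and macrophage and monocyte markers (-0.16, 4 of 16 above 0), the last inside the random range as a mean (-0.13, percentile 2.62). No cytokine or NF-kB target in these lists reached 1.5-fold.

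More genes differed by genotype than with XCL1, and part of these differences recurred in 2 pairs that share no array. With LPS, 111 genes were higher and 110 lower in the KO, and with LPS and XCL1 183 were higher and 198 lower. In both pairs 45 genes were higher and 32 lower, where independent lists would share 1.84 and 1.97. No gene was called in opposite directions, against 3.81 for independent lists. Of the 221 genes called with LPS, 196 (88.7%) had the same sign in the other pair, and Pearson's r between the genotype differences across genes was 0.527. The prefixes of the array names in the labels differ between the genotypes, with 2 prefixes and 0 shared, so a processing batch and genotype cannot be told apart. Xist differed between the genotypes too (-3.31 and -3.34). A difference in the sex of the cells may therefore coincide with genotype and cannot be told apart from it either. Whether both arrays of a genotype came from the same mice or cell preparation is not known here. If they did, a difference between preparations would recur in both pairs, so the recurrence does not show a repeat across mice. Centring each array on its gene median moved the split to 201 higher and 51 lower with LPS, 333 and 91 with LPS and XCL1, and 77 and 16 in both pairs. It added 0.100 and 0.103 to each genotype difference and list median and left the percentiles as they were.

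**Figure D2:**
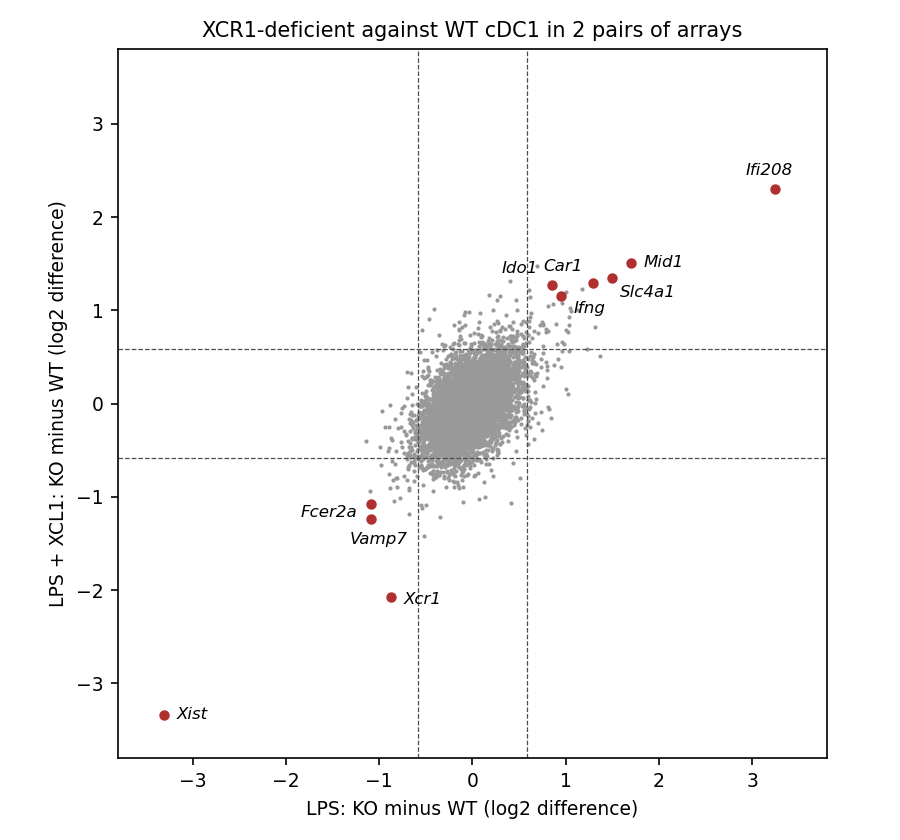
Difference between XCR1-deficient and WT cDC1 for each of 11060 genes, as log2 signal in KO minus WT, with LPS (horizontal axis) and with LPS and XCL1 (vertical axis), with dashed lines at 1.5-fold and named genes in red. Of the 221 genes beyond the lines on the horizontal axis 196 have the same sign on the vertical axis, as do 329 of the 381 beyond them on the vertical axis, with Ifi208 at 3.24 and 2.30 and Xist at -3.31 and -3.34.

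Interferon-stimulated genes had medians above the random lists in KO minus WT, and some single genes of red cells were higher. Ifi208, an interferon-inducible gene of the PYHIN family, differed by 3.24 with LPS and 2.30 with LPS and XCL1. Its WT signals lay below and just above the limit (4.86 and 5.46), so it was at least 6.38-fold higher with LPS, measured against the limit, and 4.92-fold higher with LPS and XCL1. All 25 measured interferon-stimulated genes were above 0 in both pairs, with medians of 0.31 and 0.40 (percentile 100 in both). Of these, 3 and 6 reached 1.5-fold, and 5 and 8 with centring on the gene median. Cmpk2 differed by 1.03 and 0.92, Mx2 by 0.72 and 0.85, and Rsad2 by 0.57 and 0.88. Ifng, which encodes interferon-gamma, was higher by 0.95 and 1.15, the tryptophan-degrading enzymes Ido1 by 0.85 and 1.27 and Ido2 by 1.05 and 1.03, the nitric oxide synthase Nos2 by 1.04 and 0.85, and the Fc receptor Fcgr1 by 1.00 and 1.19. Among red cell genes, named for the size of their differences, Slc4a1, the anion exchanger, was 2.82-fold and 2.55-fold higher. The red cell genes Car1 (1.29 and at least 1.15) and Rhag (at least 0.93 and 0.87) were higher too, measured against the limit where the WT signal lay below it, as were Mid1 (1.70 and 1.51), the integrin Itga1 (1.14 and 1.00) and the kinase subunit Prkar2b (0.96 and 1.08). H2-Q10, an MHC class Ib gene, gave 1.18 and 1.23, but its second probe gave -0.07 and 0.32.

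Lists of B and T cell markers and of cholesterol synthesis genes had medians below the random lists in KO minus WT. B cell markers had medians of -0.44 and -0.55 (percentile 0 in both), with 11 of 11 members below 0 and 3 and 5 of them lower, or 3 and 3 with centring. Fcer2a, the low-affinity IgE receptor, differed by -1.09 and -1.08, the B cell receptor subunit Cd79b by -0.77 and -1.01, and Cr2 by -0.98 and -0.66. T cell markers had medians of -0.41 and -0.31, with 2 of 10 members lower in each pair (1 and 2 with centring), Cd3g at -1.10 and -0.94 and Cd3e at -0.68 and -1.18. Cholesterol synthesis genes had medians of -0.28 and -0.19, with 13 of 14 members below 0 in each pair but 0 and 1 of them lower by 1.5-fold, Lss at -0.57 and -0.32 and Mvk at -0.32 and -0.62. With centring the cholesterol medians were -0.18 and -0.09, with 11 of 14 members below 0 and none lower by 1.5-fold. Scd1, a fatty acid desaturase, was at -0.89 and -0.91. Also lower were Vamp7 (-1.09 and -1.23), the kinase Yes1 (-0.84 and -1.04), the peptide transporter Slc15a2 (-0.85 and -0.82), Papss2 (-0.80 and -0.90), the basement membrane gene Nid1 (-0.81 and -0.80), Cmah (-0.82 and -0.80) and the chemokine Ccl17 (-0.66 and -0.63).

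Other cell type lists also differed between the genotypes. Neutrophil markers had medians of 0.21 and 0.28, with S100a8 at 0.26 and 1.11 and Ltf at 0.21 and 0.78. The 4 measured red cell and platelet markers had medians of 0.44 and 0.33, with 2 and 0 of them higher by 1.5-fold. An added list of 14 erythroid genes had medians of 0.07 (percentile 95.65, inside the random range) and 0.28, with 2 of its members higher in each pair. Medians of the 5 mast cell and basophil markers were 0.24 and 0.40, with Hdc at 0.79 and 0.80. Macrophage and monocyte markers (0.08 and 0.09) and cell cycle genes (0.08 and 0.06) lay above the random lists with few or no members at 1.5-fold, and with centring were at 0.18 and 0.19 and at 0.18 and 0.16. With no limit on signal, mast cell markers (0.12 and 0.15) and macrophage markers (0.05 and 0.09) lay inside the random range. With the stricter limit and LPS alone both did (0.13 and 0.0012), and cell cycle genes did with XCL1 and the mean of probe sets (0.04). With XCL1 present, 4 of 20 inflammatory cytokines were higher in the KO, namely Csf1 (0.70), Il6 (0.69), Il1a (0.64) and Il1rn (0.59), with a list median of 0.21. With LPS alone Csf1 was higher too (0.64) and Il12b was lower (-0.67). The list median of -0.04 with LPS alone lay inside the random range and was 0.02 with cyclic loess and 0.06 with centring. Cyclic loess gave 3 and centring 7 higher cytokines in the pair with XCL1. Chemokines had a median of 0.17 in that pair, with Cxcl11 at 0.89, Cxcl2 at 0.87 and Ccl2 at 0.62, while Ccl17 was lower at -0.63. The chemokine median lay inside the random range with cyclic loess (0.08, percentile 93.6). Chemokine receptors (0.13) and stromal markers (0.28) were above and ribosomal proteins (-0.10) below in that pair. With cyclic loess, receptors (0.07, percentile 91.9) and ribosomal proteins (-0.09, percentile 5.04) lay inside the random range, and so did receptors with the stricter limit (0.09, percentile 93.0). As means, receptors (0.03), stromal markers (0.03) and ribosomal proteins (-0.05) were inside. Ribosomal proteins were inside with no limit, with the stricter limit (-0.07 in both) and with the mean of probe sets (-0.08) too. The ribosomal median moved to 0.0050 with centring on the gene median, and the stromal median to -0.0307 with no limit on signal, inside the random range. The cDC1 identity list lay inside the random range in both pairs, at -0.03 in each (0.07 in both with centring), with Cd36 at -0.57 and -0.68 and Gcsam at -0.55 and -0.67. The maturation list was inside too, with Ido1 as the member higher in both pairs. Il12b, the shared subunit of interleukins 12 and 23, was at -0.67 and -0.51.

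**Figure D3:**
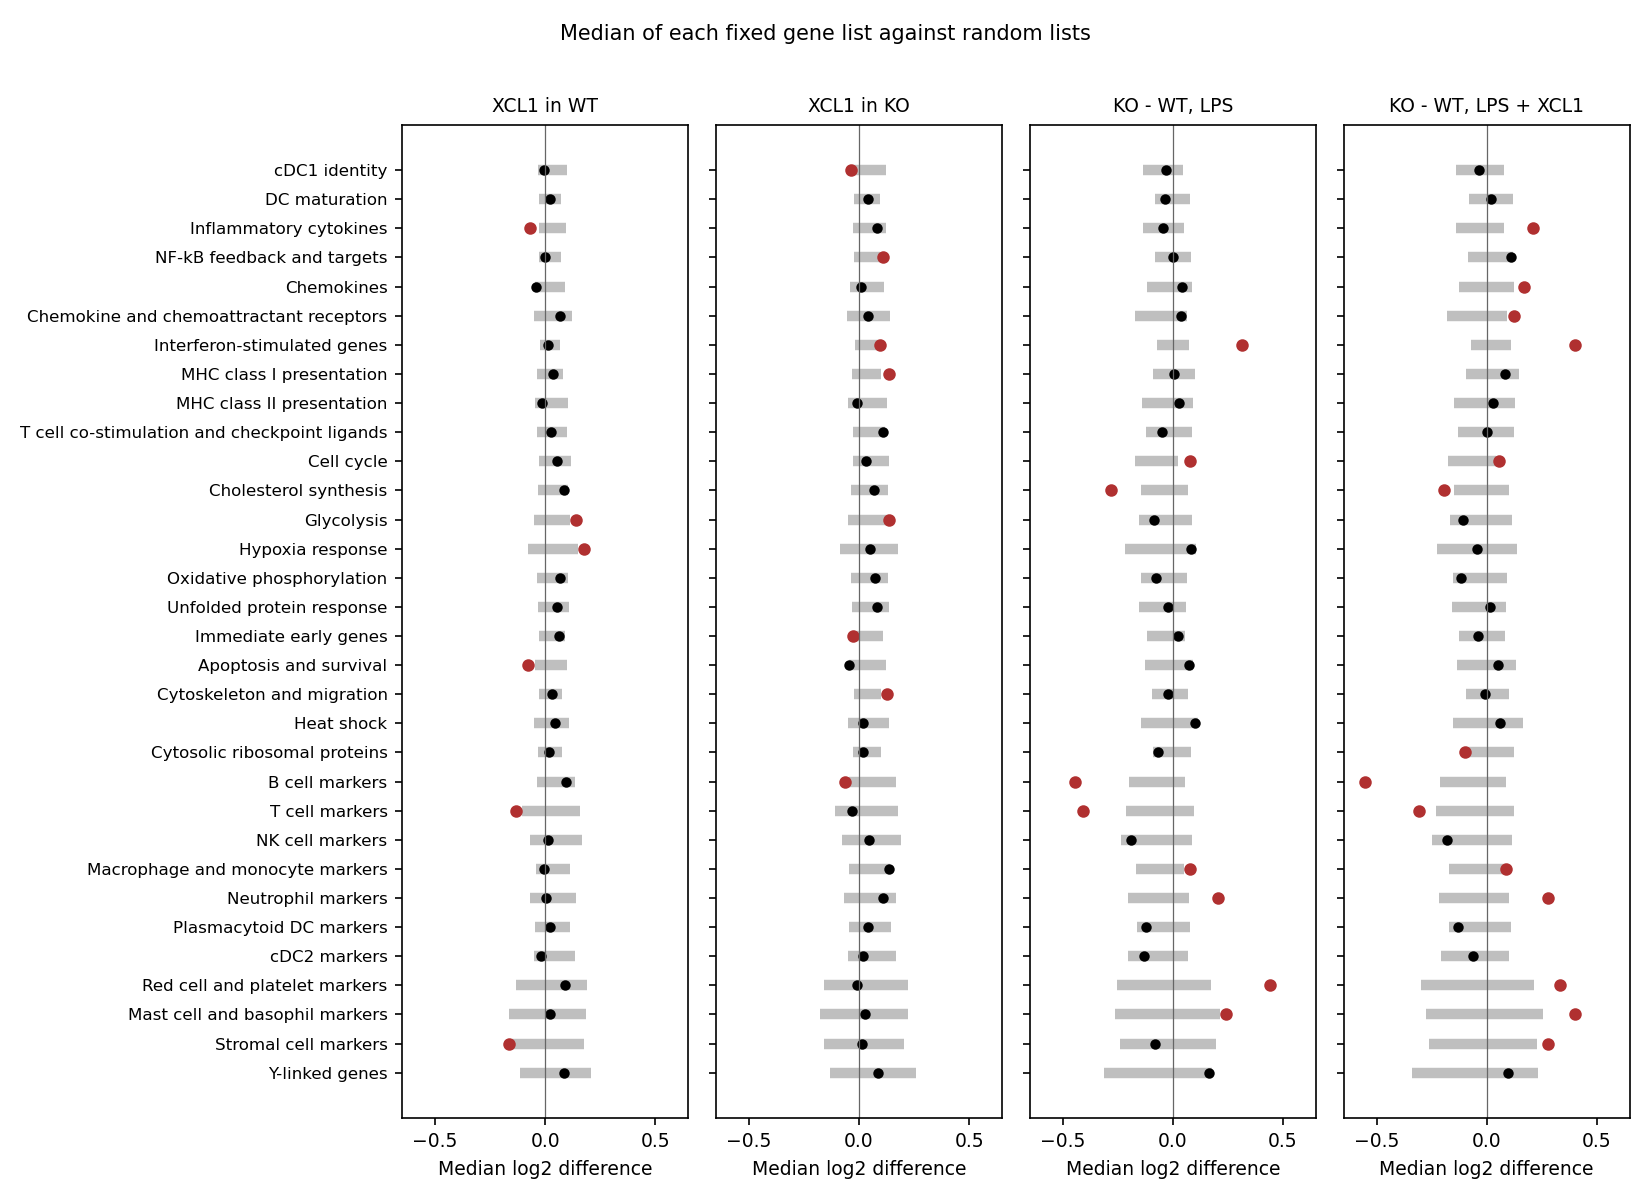
Median log2 difference of each of 32 fixed gene lists (points) in the XCL1 pairs and the genotype pairs, with grey bars for the central 95% of 10000 random lists and red points where the median lies outside. Interferon-stimulated genes lie at 0.31 and 0.40 and B cell markers at -0.44 and -0.55 in the genotype pairs.

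The expression of sex-linked genes did not match 1 sex on all arrays, although the labels give each sample as female. Xist, the RNA of the inactive X chromosome, had a signal of 7.95 and 7.91 on the WT arrays and 4.64 and 4.57 on the KO arrays, the latter below the limit. Measured against the limit it was at least 5.75-fold and 5.56-fold lower in the KO. Of the Y-linked genes, 4 had signals well above the limit on all 4 arrays, while Zfy2 and Usp9y were below the limit on each. Eif2s3y had signals of 8.57 and 8.80 in WT and 8.73 and 8.89 in KO, and Uty had 8.27 and 8.27 in WT and 8.46 and 8.41 in KO. Kdm5d lay between 7.01 and 7.16. Srsy had 7.24 and 6.80 in WT and 7.15 and 7.18 in KO. The other 2 measured genes of the chromosome were dim. Sly, which has several copies, lay below the limit on all arrays but the KO with LPS and XCL1 (5.45), and with signals raised to the limit it differed by 0 and 0.02 between the genotypes. Sry was at -0.03 and -0.15. Genes on chromosome X made up 7 of the 77 genes that differed between the genotypes in both pairs. That was 2.24% of the 313 measured on X, against 0.696% of all genes.

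**Figure D4:**
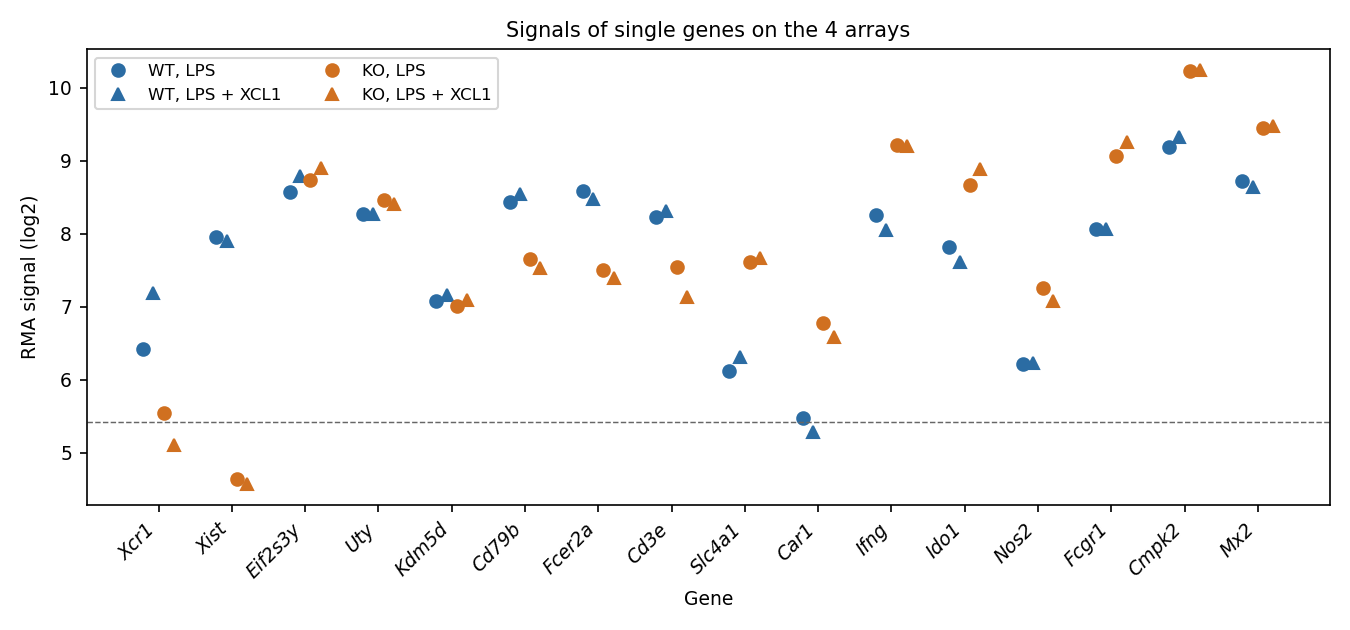
Log2 RMA signal of single genes on the 4 arrays, with WT in blue and KO in orange, circles for LPS, triangles for LPS and XCL1, and a dashed line at the limit on signal of 5.43. Xist lies at 7.95 and 7.91 in WT and below the line in KO, while Eif2s3y lies between 8.57 and 8.89 on all 4 arrays.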

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

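Ccr8 and Ptma-ps2 differed at least 1.5-fold in opposite directions when XCL1 was added to WT and to KO cells. Ccr8, a chemokine receptor gene whose start lies within 5 Mb of Xcr1, was at -0.71 in WT and 0.71 in KO, a difference of -1.43. Ptma-ps2, a pseudogene of prothymosin alpha, was at -0.73 in WT and 0.65 in KO, a difference of -1.38. With signals below the limit raised to it, neither reached 1.5-fold in either pair, with Ccr8 at -0.13 and 0.43 and Ptma-ps2 at 0 and 0.10. With 1 array per group the difference between WT and KO was not tested. Independent lists of these lengths would share 0.303 genes in opposite directions, against the 2 seen.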

How the results depend on the processing

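Leaving out the X and Y genes or the lymphoid and red cell lists, and raising dim signals to the limit, were chosen after seeing the data; the other settings were fixed before. Counts of genes depended on the threshold and on the limit on signal. The 2-fold threshold gave 2 genes for XCL1 in WT, 6 for XCL1 in KO, 23 and 41 for genotype with LPS and with LPS and XCL1, 21 for the difference between WT and KO, and 10 in both genotype pairs. With no limit on signal, which adds genes, the counts were 176 for XCL1 in WT, 212 for XCL1 in KO, 340 for genotype with LPS and 726 for WT minus KO. The stricter limit, which removes genes, gave 11, 26, 103, 193 and 71 for XCL1 in WT, XCL1 in KO, both genotype pairs in turn and WT minus KO. Signals below the limit raised to it gave 27, 65 and 205 for XCL1 in WT, XCL1 in KO and WT minus KO. Predicted genes and small RNAs kept raised the XCL1 counts to 96 in WT and 183 in KO. Centring on the gene median shifted all genotype differences by 0.100 and 0.103 and XCL1 differences by -0.07, which moved the splits as given in the report, and cyclic loess gave 30 higher and 29 lower genes for XCL1 in WT. Of the 40 list medians outside the random range, 21 fell inside it with some alternative, and some changed sign. Immediate early genes in KO moved to 0.0385 with the stricter limit and 0.0137 as a mean, B cell markers in KO to 0.0031 as a mean, ribosomal proteins with LPS and XCL1 to 0.0050 with centring, and stromal markers there to -0.0307 with no limit. Medians inside the range changed sign too, among them cDC1 identity by genotype (0.07 in both pairs with centring) and cytokines by genotype with LPS (0.02 with cyclic loess, 0.06 with centring). With centring the sign changes are those uniform shifts, with percentiles unchanged, and the cause of the others was not tested. The other 51 counts and summary values stayed within 1.5 times the main count or within the SD of 0.196 in the KO pair, the correlation of XCL1 effects ranged from 0.104 to 0.136, and of the remaining list values 186 moved by more than the SD of random lists and 759 did not. Without X and Y genes 208, 365 and 69 genes differed by genotype with LPS, with LPS and XCL1 and in both pairs, and without the lymphoid and red cell lists 214, 374 and 72. With the mean of probe sets, Gemin6 moved to 0.63, Snhg17 to 0.74, Mid1 to 1.89 and H2-Q10 to 0.55. The labels hold no replicate numbers for a paired fit. An additive model pairing the genotypes by treatment was not fitted, and no array was left out. Signals near the limit carry most called XCL1 genes, so dim genes limit these counts.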

Other observations

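Small nucleolar RNAs, which guide the modification of ribosomal RNA, had a higher median in the KO with LPS and XCL1 than with LPS alone. Most of their probe sets stayed within 1.5-fold, and the median was not placed among random lists. The median of 78 probe sets for these RNAs was 0.39 above the KO array with LPS, with 21 higher and 0 lower at 1.5-fold. In WT the median difference between the arrays with and without XCL1 was 0.01, with 0 higher and 0 lower. Against the WT array with XCL1 the KO array was at 0.24, and with LPS alone the KO was at -0.15. These probe sets were left out of the counts of genes and were looked at after the data were seen, because Snhg17, which hosts such RNAs, was among the genes higher in the KO with XCL1.

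Some markers of plasmacytoid DCs were below 0 in KO minus WT in both pairs, though the list lay inside the random range at -0.12 and -0.13. Siglech was at -0.52 and -0.57, Ccr9 at -0.58 and -0.49 and Spib at -0.66 and -0.47, while Tcf4 was at 0.16 and 0.31. Of the 12 markers 3 and 4 were above 0. At 1.5-fold, Spib was lower with LPS, and with LPS and XCL1 Bst2 was higher (0.78) and Ly6d (-1.22) and Cox6a2 (-0.71) were lower. NK cell markers were inside as well, at -0.19 and -0.18. Neither list stood apart from random lists.

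Tests for the sex label, the female-cell and exchanged-array explanations, for the share of the main cell type and for the batch were chosen only after the results were seen, the one for the main cell type in place of a test on an erythroid list that had left the question open. The first pattern is Xist, at least 5.75-fold and 5.56-fold lower on the KO arrays when measured against the limit, beside the Y-linked genes Eif2s3y, Uty and Kdm5d, which were bright on all 4. If WT and KO arrays had been exchanged, Xcr1 would be higher on the arrays labelled KO, but it was at -0.87 there with LPS and -1.76 with LPS and XCL1, the latter measured against the limit. Both are beyond the SD of 0.196 in the KO pair, but that SD is over all genes. Xcr1 itself differed by 0.77 between the WT arrays and by -0.43 between the KO arrays, so the SD is no measure of its own spread. Both KO signals of Xcr1 lay below both WT signals. Female cells only on the KO arrays, as the label has it, is argued against, since the Y-linked list had median signals of 8.46 and 8.41 there while Xist lay below the limit, at 4.64 and 4.57. If WT samples held female cells mixed with male cells and KO samples fewer or none, Y-linked genes would be higher in the KO. Their median was 0.164 with LPS and 0.098 with LPS and XCL1. The spread was 0.113, the SD of the KO pair over all genes divided by the square root of the number of Y-linked genes. So 1 pair passes that spread and the other does not. With centring the medians were 0.264 and 0.201, both past 0.113, and with cyclic loess they were 0.197 and 0.109. The outcome therefore depended on the scaling. On the WT arrays Xist, at 7.95 and 7.91, lay beside Eif2s3y at 8.57 and 8.80, as a mixture would give. A mixture on the WT arrays stays open.

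The second pattern is lower B and T cell markers with higher red cell genes in the KO. A smaller share of the main cell type would move the markers of every other type alike. Neutrophil markers were at 0.206 and 0.279 and red cell and platelet markers at 0.44 and 0.33. B cell markers went the other way, at -0.44 and -0.55. The B cell and red cell lists are the pattern itself, and the neutrophil values had been seen. These values are therefore no separate test of that share. Only 4 red cell and platelet markers were measured, 2 and 0 of them higher by 1.5-fold. Fewer B and T cells among the KO cells is a candidate explanation for the first part. An added list of 20 other B and T cell genes had medians of -0.287 and -0.314 (percentile 0 in both), with 18 and 19 members below 0 and 0 and 2 lower by 1.5-fold. None of them are in the fixed lists, but some, such as Cd4, are also made by dendritic cells. The list was added after the fixed markers had been seen on the same 4 arrays. A batch would lower it too, so it does not single out cell numbers. The abundant B cell genes Cd79a and Ms4a1 had signals of 8.92 and 8.83 on the WT array with LPS, and the labels name no sort. An added list of 14 erythroid genes, made without the genes that drew attention, was at 0.07 with LPS (percentile 95.65, inside the random range) and 0.28 with LPS and XCL1 (percentile 100), so on that list the second part held in 1 pair only. A batch or a difference in the sex of the cells cannot be told apart from genotype, since the 88.7% of genes that kept their sign would follow from any of them.

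The third pattern is higher interferon-stimulated genes in the KO. Cyclic loess left the list's medians at 0.319 and 0.375, above the random lists in both pairs. It was run on the deposited values, which RMA had already equalised, so it cannot decide whether that earlier normalization is the source. More interferon-gamma signalling in the KO samples is a hypothesis on which the lists were divided. The fixed list of MHC class I presentation, which holds Psmb9 and Tap1, was at 0.004 and 0.083. That of MHC class II presentation, which holds Ciita, was at 0.026 and 0.027. Both lay inside the random range in both pairs. A list of 20 interferon-gamma-inducible genes, added after seeing the data and made without Ifng, Ido1, Nos2 and Fcgr1, had medians of 0.172 and 0.351 (percentile 100 in both), with 16 and 18 of 20 members above 0, 0 and 3 at 1.5-fold, Gbp7 at 0.40 and 0.83 and Gbp8 at 0.36 and 0.95. Of its genes 4 (Cxcl9, Ciita, Psmb9 and Tap1) are also in fixed lists, and some answer to type I interferon as well. Batch, the sex of the cells and genotype cannot be told apart here, so whether the receptor's loss is the source stays untested.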
